A study of Homo sapiens with 4 samples.

How the data were processed

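Polyadenylated RNA from HEK293 cells, a human embryonic kidney line that the culture protocol in the labels calls HEK293T, was measured in 4 long-read libraries, 1 for each combination of fixation (0.5% formaldehyde, FA, or the cleavable crosslinker DSP) and primary antibody (anti-G3BP1 or rabbit IgG as the control). Per the labels' protocols, RNA was extracted with TRIzol and the libraries were made with the PacBio Kinnex full-length RNA kit. The submitters' processing notes name minimap2 2.28, bedtools 2.31.1 and the genome builds hg38 and GRCh38, with no role for either tool. The program that counted transcripts and the annotation release are not given in the sources used here. The isoform-level editing tables that the labels mention were not analysed here.

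Each deposited file lists 246624 transcripts with 1 value each and a further entry of unassigned reads. Per the file headers the values are TPM. The deposited values were checked and are CPM, read counts scaled to a fixed total, because 1 read was worth the same amount for every transcript and no term for transcript length was present. The deposited total included the unassigned reads. They made up 55.8% of the FA anti-G3BP1 file, 56.8% of the FA IgG file, 17.4% of the DSP anti-G3BP1 file and 53.0% of the DSP IgG file. The 37 mitochondrial transcripts were listed at 0 in all 4 libraries.

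The low values showed how each deposited file had been built. Every value of the FA anti-G3BP1 and FA IgG files was the mean of 2 tables of whole reads, which were recovered for 100.0% of the values, with a single solution for 99.99% and 99.88% of them. The 2 tables held 1711036 and 1719819 assigned reads in FA anti-G3BP1 and 2189271 and 1553350 in FA IgG. What the tables stand for (sequencing runs, libraries or cultures) is not given in the sources used here, so they were not counted as replicates in the main tests. The DSP IgG file held whole reads of 1 table, 2758149 of them assigned. The DSP anti-G3BP1 file held reads in steps of 0.01 read, with 23.2% of its values whole and 5683570 reads assigned. This difference in counting lies in 1 of the 4 files and cannot be removed. The recovery of the tables was tested on simulated tables of the same totals and returned 100.0% and 99.997% of the values correctly. It needs tables whose totals differ.

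Values were rescaled to CPM of assigned reads, so that the entry that names no transcript stayed out of the library size. This departs from the plan. The design written before the data were examined had taken the deposited values as the scale, under the name TPM and with the unassigned reads in the total. The scale was changed when the unassigned shares had been read and before any comparison was computed. The choice decides the main count: limma called 2751 genes between the fixations on assigned reads and 0 on the deposited scale, where 3190 passed an unadjusted p of 0.05. On the deposited scale the low unassigned share raised the DSP anti-G3BP1 library alone, and in a model with separate fixation and antibody terms such a shift of 1 library enters the residual spread. TMM rescaling, an alternative planned before the data were examined, gave 2771.

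Transcript identifiers were matched to GENCODE 29, which held 203462 of them (82.5%) and 95.4% to 98.1% of the assigned reads of each library. Names, positions on GRCh38 and lengths were taken from there, and gene values are sums over a gene's transcripts. How the authors divided reads between overlapping genes, pseudogenes and near-identical copies is not given in the sources used here, so values of genes with close copies, ribosomal protein genes among them, are uncertain in that respect. No column of the files was left unused.

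Genes and transcripts with a mean of at least 5 CPM over the 4 libraries were tested, 10185 genes and 16411 transcripts. The test was limma with a mean-variance trend on log2(CPM + 1), with a fixation and an antibody term and Benjamini-Hochberg adjustment, called at an adjusted p of 0.05. Folds in the text are on the log2(CPM + 1) scale, which understates the change of low genes. With 1 library per group the model leaves 1 residual degree of freedom. The spread behind each standard error is the disagreement between the antibody arms, moderated across genes, and p-values measure only that spread, which may be technical, since nothing in the labels says that the libraries came from separate cultures. Comparisons of single libraries had no planned test and count genes at least 2-fold apart. edgeR on recovered tables was added for DSP IgG against FA IgG and for FA anti-G3BP1 against FA IgG. The spread in those fits comes only from the tables inside the FA files, so their p-values measure no spread between samples. No label says whether FA and DSP cells were handled on the same day, so fixation and batch cannot be told apart.

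The genes named in the text follow a rule set before the data were examined. It takes the 12 highest and 12 lowest passing genes between the fixations and the 8 highest and 8 lowest between the antibodies. It adds the 3 highest and 3 lowest genes between antibodies within a fixation, up to 3 members of each gene list with the largest difference between the fixations, 8 genes for transcript shares between fixations and 4 between antibodies. It also takes G3BP1, its paralog G3BP2 and the 5 most abundant genes, of which 3 are reported. Genes without a symbol in the annotation are not named. Some genes and transcripts that the rule selects are not reported, so fewer are named than the rule gives. The 27 gene lists, the test, the filter, the pseudocount of 1 and the size thresholds were set before the data were examined. For each list the text gives the median difference, the calls adjusted over all genes and the calls adjusted over the list alone. A list's median was also placed among the medians of 10000 random lists of the same size matched on mean expression, and among 10000 matched on transcript length and expression. That comparison was added after the length differences were seen.

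Transcript shares were computed as a transcript's part of its gene's CPM. The 3844 genes used had at least 20 CPM in every library and several transcripts with reads in any library. A gene was counted when a transcript's share differed by at least 20 percentage points in the same direction in both arms. Intervals for shares are Wilson intervals at 95% on recovered reads, pooled over both tables for the FA libraries. They cover counting error only, because the reads carry no stated molecular identifiers.

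Alternatives planned before the data were examined were pseudocounts of 0.1 and 5, no filter or a filter at 20 CPM, TMM factors, totals without mitochondrial, ribosomal protein and MALAT1 reads, limma without the trend, models with 1 term, and the most abundant transcript of each gene only. The deposited scale, planned as the main scale, was run as an alternative once the scale had been changed. Added after the files were read were at least 1 CPM in every library, genes with 1 listed transcript, each library left out, and each library's length trend removed. edgeR's quasi-likelihood test and DESeq2 had been planned only if all values proved to be whole reads. That condition was not met by the DSP anti-G3BP1 file, so they were run as added alternatives with its fractions rounded. edgeR was also run on the 5 recovered tables of whole reads alone. The software was R 4.3.3 with limma 3.58.1, edgeR 4.0.16 and DESeq2 1.42.0, and Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

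The tests were tried on simulated data with 100 genes of 10185 changed 2-fold and 100 changed 4-fold, drawn at the libraries' real means and totals with a dispersion of 0.05. For the fixation term, limma recovered 32% of the 2-fold and 97% of the 4-fold changes, and for the antibody term 27% and 97%. edgeR recovered 31% and 97% for the fixation term. On the recovered tables edgeR found 20% and 89% for the antibodies within FA and 10% and 76% for DSP IgG against FA IgG. Between 4 and 9 unchanged genes were called in each simulation. The spread in the data was larger than simulated, with a coefficient of variation of 0.453 over the recovered tables and 0.574 between those of FA IgG, so these percentages are not the recovery in these libraries.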

Results

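HEK293 cells were profiled by long-read MAPIT-seq, in which an antibody brings a fusion of the cytidine deaminase rAPOBEC1, an antibody-binding pAG domain and the adenosine deaminase hADAR2 to RNAs near the antibody's target in fixed cells. The target was G3BP1, a core protein of stress granules, and rabbit IgG served as the control. Cells were fixed with formaldehyde (FA) or with DSP, a cleavable amine-reactive crosslinker, which gave 4 libraries, 1 for each fixation and antibody. The series was made to resolve RNA binding at the level of isoforms. The deposited values used here are transcript abundances, and editing itself was not analysed here. Reads assigned to transcripts numbered 3430855 in FA anti-G3BP1, 3742621 in FA IgG, 5683570 in DSP anti-G3BP1 and 2758149 in DSP IgG. EEF2, a translation elongation factor, H3-3B, a histone H3.3 gene, and IRS4, an insulin receptor substrate, were among the 5 genes with the most reads. EEF2 stood at 5380 CPM in FA anti-G3BP1, 5438 in FA IgG, 1851 in DSP anti-G3BP1 and 2970.5 in DSP IgG.

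The largest comparison was between the fixations. Genes of ribosomal proteins and of oxidative phosphorylation were lower in DSP than in FA, while the chaperones HSPA5 and HSPD1 and G3BP1 itself were higher. HSPA5, the main chaperone of the endoplasmic reticulum, rose 6.32-fold (log2 difference 2.66, SE 0.38, adjusted p 0.00217 by limma). HSPD1, a mitochondrial chaperonin, rose 5.64-fold (2.50, SE 0.34). ALDOA, a glycolytic aldolase, was 6.71-fold lower in DSP (log2 difference -2.75, SE 0.35). RPL35, a protein of the large ribosomal subunit, was 19.6-fold lower (-4.29, SE 0.47).

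Of 10185 genes tested with limma, 2751 passed an adjusted p of 0.05, 1314 higher and 1437 lower in DSP, and each differed by at least 1 on the log2 scale. edgeR called 1907 genes (1010 higher and 897 lower) and DESeq2 2415 (1392 and 1023). With each library's length trend removed limma called 2493 (1367 and 1126). On the scale planned beforehand, with unassigned reads in the total, limma called 0 genes, 3190 had an unadjusted p under 0.05 and the median gene shifted by 0.48, so no gene described below as risen or fallen passed on that scale. A model with the fixation term alone, the only form that 3 libraries allow, called 2559 genes on all 4 libraries, 778 without FA anti-G3BP1, 487 without FA IgG and 5293 without DSP IgG. With both terms limma called 901 genes without its trend and 178 among 772 genes with 1 listed transcript (33 higher and 145 lower).

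Cytosolic ribosomal protein genes had a median log2 difference of -2.72 between DSP and FA. Of the 74 tested, 68 fell and 0 rose, and 69 fell when adjusted over the list alone. RPS19, whose most abundant transcript has 2359 bases, was 13.7-fold lower (log2 difference -3.77, SE 0.36). Nuclear-encoded genes of oxidative phosphorylation had a median of -2.85. Of 64 tested, 54 fell and 1 rose, or 57 and 2 adjusted over the list alone. NDUFA13, a subunit of complex I, was 19.0-fold lower (-4.25, SE 0.49), and UQCRH of complex III and NDUFB2 of complex I stood at -4.10 (SE 0.54) and -3.97 (SE 0.51). Mitochondrial ribosomal protein genes had a median of -2.06, with 36 of 49 lower and 0 higher, and 39 lower adjusted over the list alone. MRPL51 was 13.5-fold lower (-3.76, SE 0.45), and MRPL41 10.4-fold. Translation factors with 5' TOP motifs had a median of -1.42. Of 18, 9 fell and 0 rose, and 11 fell adjusted over the list alone, among them NACA (-2.24, SE 0.36), which protects nascent chains, and RACK1 (-2.10, SE 0.39), a ribosomal scaffold.

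These genes are mostly short, and short transcripts were lower in DSP in general. Random lists matched on length and expression had medians of -1.57, -1.44, -1.33 and -0.51 for the 4 groups in the order given. With each library's length trend removed, limma called 21 ribosomal protein genes, 17 of oxidative phosphorylation, 11 mitochondrial ribosomal protein genes and 5 translation factors lower, with medians of -0.53, -0.78, -0.57 and -0.57. RPL35, UQCRH, NDUFB2 and RACK1 no longer passed. Between the 2 recovered tables inside FA IgG the same lists were apart by medians of -1.96, -2.21, -1.47 and -0.94. RPL35 stood at 45.7 and 637 CPM and NDUFA13 at 24.7 and 298 CPM in those tables. RPS19 stood at 103 and 596 CPM there, although genes with a main transcript of 2 to 4 kb had a median of 0.28. The call of RPS19 stayed with the length trend removed (-3.84), which rests on the annotated length. Whether its reads had that length was not tested. All 15 mitochondrially encoded genes of the list were listed at 0 in every library and none was tested.

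Genes of stress granule proteins had a median of 0.88. Of 25 tested, 9 rose and 1 fell, with the same counts adjusted over the list alone, and 8 rose and 4 fell with the length trend removed. FMR1, the fragile X protein, rose 6.37-fold (log2 difference 2.67, SE 0.68), by 1.08 between the IgG libraries and 4.26 between the anti-G3BP1 libraries. ATXN2L, a paralog of ataxin-2, was 6.39-fold lower (-2.68, SE 0.42). SR proteins and hnRNPs, which bind pre-mRNA, had a median of 0.83, and 10 of 30 rose and 1 fell (14 and 1 adjusted over the list alone). The splicing repressor PTBP2 rose 11.9-fold (3.58, SE 0.86; 1.93 in IgG and 5.23 in anti-G3BP1), and HNRNPR and HNRNPM rose by log2 differences of 1.90 (SE 0.33) and 1.88 (SE 0.33). Length-matched random lists had medians of 0.10 for both groups. Between the recovered tables of FA IgG these groups were apart by medians of 0.37 and 0.39, against 0.70 and 0.64 between the IgG libraries. Very long mRNAs had a median of 0.74 against 0.13 in length-matched random lists. Of 38, 5 rose and 1 fell, or 4 and 1 adjusted over the list alone. ASPM, a spindle protein, rose 4.47-fold (2.16, SE 0.42), VPS13D, a lipid transfer protein, had a log2 difference of 3.03 (SE 0.78), and SRRM2, a spliceosome protein, was 4.72-fold lower (-2.24, SE 0.34). Without DSP anti-G3BP1, limma called 1 very long mRNA higher and 1 lower, and the median was 0.25 between the IgG libraries.

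**Figure D1:**
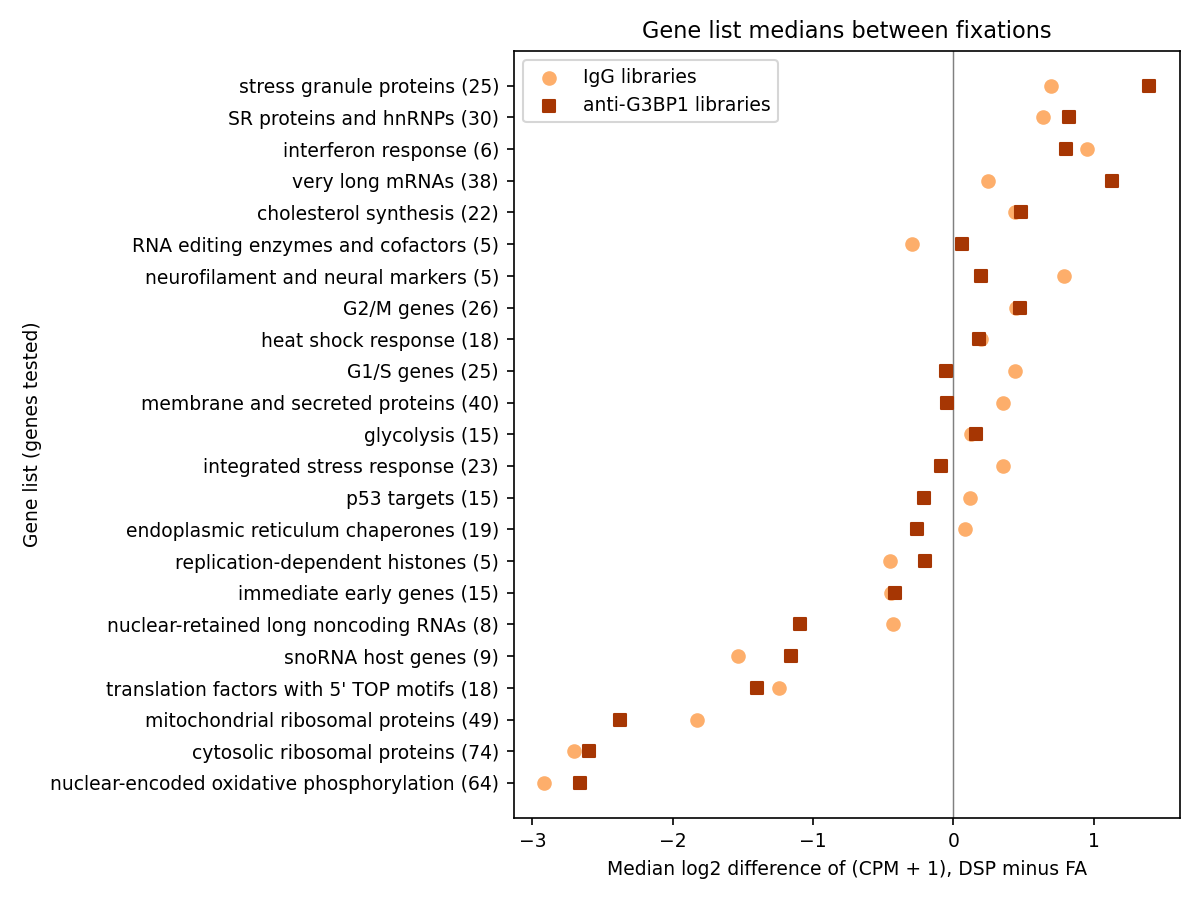
Each point is the median log2 difference of (CPM + 1), DSP minus FA, over the tested genes of a list, with circles for the IgG libraries and squares for the anti-G3BP1 libraries (1 library per group, number of genes in brackets). The ribosomal and oxidative phosphorylation lists lie at -1.83 or below in both pairs, and the stress granule list lies at 0.70 and 1.40.

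Genes of cholesterol synthesis had a median of 0.73, with 7 of 22 higher and 4 lower (10 and 6 adjusted over the list alone). With the length trend removed the median was 0.43, with 3 higher and 1 lower, and between the IgG libraries it was 0.44. Between the 2 recovered tables inside FA IgG the list was apart by a median of 0.63. EBP, a sterol isomerase, was 5.41-fold lower (log2 difference -2.44, SE 0.42). G1/S genes had a median of 0.26, with 7 of 25 higher and 4 lower and the same counts adjusted over the list alone. MCM3, a subunit of the replicative helicase, rose 20.2-fold (4.33, SE 0.62; 2.75 in IgG and 5.92 in anti-G3BP1), and CCNE2, cyclin E2, rose 9.46-fold (3.24, SE 0.37). G2/M genes had a median of 0.46, with 8 of 26 higher and 3 lower (10 and 3 adjusted over the list alone). It was 0.27 among genes with at least 1 CPM in every library, and 10 were higher and 0 lower with the length trend removed. The kinesin KIF11 rose 13.3-fold (3.73, SE 0.93), and the short transcripts of CKS2 and UBE2C were 8.03-fold and 5.27-fold lower. Membrane and secreted proteins had a median of 0.16 (-0.07 with the length trend removed), with 11 of 40 higher and 6 lower (12 and 9 adjusted over the list alone). TFRC, the transferrin receptor, stood at 4.36 and 1.60 CPM in FA and at 401 and 35.2 CPM in DSP (5.01, SE 0.63), and EGFR and IGF2R also rose (4.44, SE 1.00, and 4.32, SE 0.99). Between the recovered tables of FA IgG the G1/S, G2/M and membrane lists were apart by medians of 0.07, 0.29 and 0.13. Between the IgG libraries these medians were 0.44, 0.45 and 0.36.

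Stress-response lists moved both ways. Of 18 heat shock genes (median 0.34, 0.20 between the IgG libraries and 0.84 on the deposited scale), 5 rose and 3 fell, or 7 and 3 adjusted over the list alone and 5 and 1 with the length trend removed, and HSPE1, the partner of HSPD1, was 8.56-fold lower (-3.10, SE 0.42). HSPB1, a small heat shock protein, was 6.49-fold lower (-2.70, SE 0.83). Of 23 integrated stress response genes (median 0.13), 5 rose and 2 fell, or 7 and 3 adjusted over the list alone. AARS1, the alanyl-tRNA synthetase, and the transcription factor CEBPG rose by 2.95 (SE 0.40) and 2.85 (SE 0.48), and CEBPB, another C/EBP factor, was lower (-3.91, SE 0.63). Of 19 endoplasmic reticulum chaperone genes (median -0.10, and 0.40 on the deposited scale), 5 rose and 3 fell, or 5 and 4 adjusted over the list alone, with SDF2L1 and MANF lower at -3.05 (SE 0.49) and -2.85 (SE 0.52). Of 15 p53 targets (median -0.08, and 0.41 on the deposited scale), 3 rose and 1 fell over all genes and adjusted over the list alone, including SESN1 (2.66, SE 0.45), TNFRSF10B (1.80, SE 0.48) and BAX (-2.62, SE 0.46). Of 15 immediate early genes (median -0.37, and 0.13 on the deposited scale), JUND fell (-2.91, SE 0.52) and IER2 rose (2.35, SE 0.67; 0.98 in IgG and 3.73 in anti-G3BP1), with the same 1 and 1 adjusted over the list alone, and 1 higher and 5 lower with the length trend removed. Of 6 interferon response genes (median 0.81), 2 rose and 0 fell by all genes and adjusted over the list alone, IFIT5 (1.29, SE 0.43) among them, which did not pass with the length trend removed (0.78, adjusted p 0.215). Between the recovered tables of FA IgG these lists, in the order given, were apart by medians of 0.01, 0.40, 0.42, 0.57, 0.21 and 0.18. Between the IgG libraries their medians were 0.20, 0.36, 0.08, 0.12, -0.44 and 0.95.

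Of 15 glycolysis genes (median 0.15, and -0.10 among genes with at least 1 CPM in every library), 4 rose and 2 fell, or 6 and 3 adjusted over the list alone. The median of this list was 0.13 between the IgG libraries and 0.52 between the recovered tables of FA IgG. HK1 rose 7.38-fold (2.88, SE 0.45), and HK2 was listed at 0 in both FA libraries and at 123 and 1.81 CPM in DSP (adjusted p 0.0506). Nuclear-retained long noncoding RNAs had a median of -0.76, and 3 of 8 fell by all genes and adjusted over the list alone. They were NEAT1, the scaffold of paraspeckles (-1.66, SE 0.40), GABPB1-AS1 (-1.64, SE 0.42) and OIP5-AS1 (-1.26, SE 0.37). With edgeR the calls of GABPB1-AS1 and OIP5-AS1 were lost. Of 9 snoRNA host genes (median -1.42, and 0.76 with the length trend removed), 3 fell over all genes and adjusted over the list alone. They included DANCR (-2.97, SE 0.45), SNHG29 (-2.12, SE 0.39) and SNHG3 (-1.89, SE 0.40). Of 5 replication-dependent histone genes (median -0.33, and 0.14 on the deposited scale), H4C3 fell (-3.45, SE 0.55), the single call also adjusted over the list alone. Of 5 RNA editing enzymes and cofactors (median 0.51, and 0.14 with the length trend removed), SYNCRIP rose (2.84, SE 0.48) and APOBEC3C fell (-1.92, SE 0.50), 1 each way also adjusted over the list alone. The median of that list was -0.29 between the IgG libraries and -0.51 between the recovered tables of FA IgG. With the length trend removed, several short transcripts reported as fallen no longer passed, among them CKS2, UBE2C, HSPE1, HSPB1, SDF2L1, MANF, BAX, DANCR, SNHG29 and H4C3. H4C3 also held 154 and 3 reads in the 2 tables of FA anti-G3BP1 and 6 and 185 in those of FA IgG.

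Markers of other cell types were few. Of the blood cell markers 0 were tested, and of the fibroblast markers 2 were, FBLN1 (log2 difference -1.14, SE 0.37, adjusted p 0.045) and COL1A1 (-1.47, SE 0.62, adjusted p 0.102), with 1 lower over all genes and 2 adjusted over the list alone. Of the simple epithelial markers 2 were tested, and KRT18 fell (-1.49, SE 0.42) while CDH1 did not pass, with 1 also adjusted over the list alone. Of 5 neural markers (median 0.46, and -0.04 with the length trend removed), UCHL1 fell (-1.74, SE 0.46), and 1 rose and 1 fell adjusted over the list alone. KRT18 and UCHL1 did not pass with the length trend removed. All p-values in these paragraphs came from limma.

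**Figure D2:**
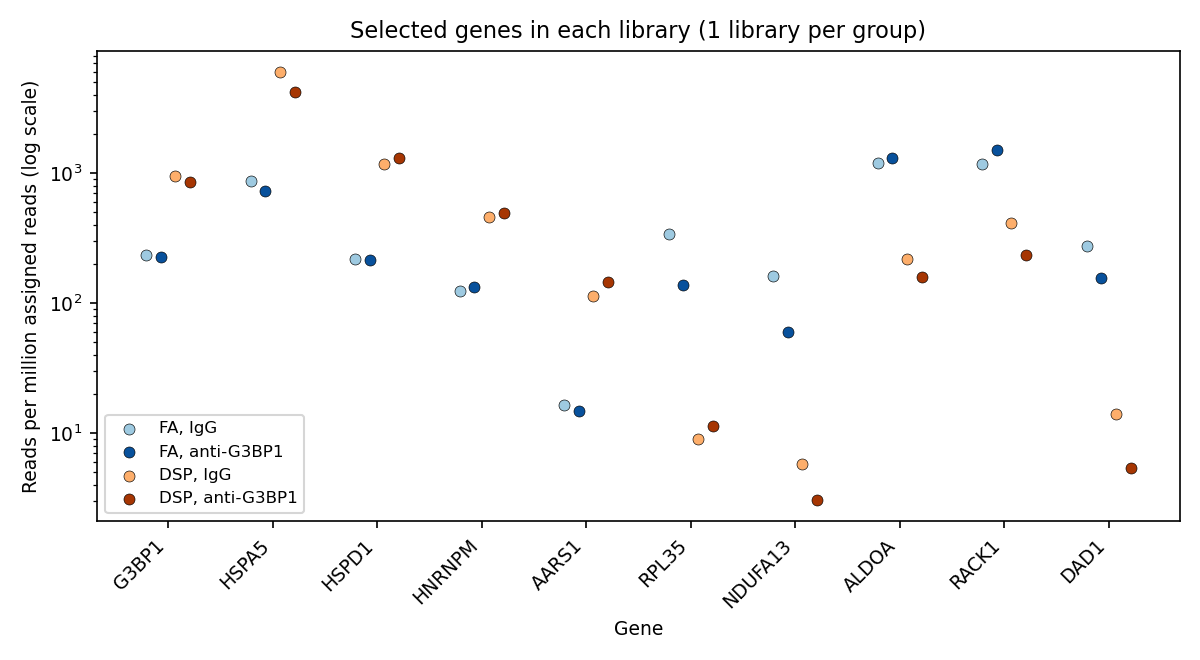
Each point is a gene's level in CPM (log axis) in 1 library, for G3BP1 and 9 other genes reported between the fixations. HSPA5 lies at 723 and 866 CPM in FA and at 4205 and 5961 CPM in DSP, and DAD1 lies at 156 and 273 CPM in FA and at 5.38 and 14.1 CPM in DSP.

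The 12 genes with the largest rise included some that the FA libraries hardly held. RBAK, a zinc finger partner of the retinoblastoma protein, was listed at 0 in both FA libraries and at 111 and 88.1 CPM in DSP. FIGN, a microtubule-severing ATPase, SLITRK5, a neuronal membrane protein, ZNF629, KBTBD8, a ubiquitin ligase adaptor, and E2F2, a cell cycle transcription factor, were also listed at 0 in both FA libraries. CNOT6L, a deadenylase, went from 0.29 and 0.23 CPM to 79.2 and 119 CPM, and ANKFY1, an endosomal protein, from 2.04 and 1.75 CPM to 153 and 234 CPM (log2 difference 6.04, SE 0.49, adjusted p 0.00107 by limma). GANAB, the catalytic subunit of glucosidase II, rose 50.1-fold (5.65, SE 0.46), and UHRF1, which maintains DNA methylation, rose by 4.86 (SE 1.22), with 5.80 CPM in DSP IgG and 191 CPM in DSP anti-G3BP1 (differences 2.13 and 7.59).

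The 12 genes with the largest fall included some absent from DSP. ZIC5, at 64.0 and 71.3 CPM in FA, and FOXJ2, KLF13 and IRAK1BP1 were listed at 0 in both DSP libraries. They were also absent from single FA tables, ZIC5 with 0 and 218 reads in the 2 tables of FA anti-G3BP1 and 313 and 0 in those of FA IgG, and FOXJ2, KLF13 and IRAK1BP1 with 146 and 0, 105 and 0, and 0 and 47 reads in those of FA IgG. USF3 had 127 and 0 reads in the tables of FA anti-G3BP1. ZNF703 stood at 189 and 178 CPM in FA and at 0 and 34.1 CPM in DSP (log2 difference -4.96, SE 0.93), and BHLHE40 and USF3 were 23.9-fold and 21.1-fold lower. The short transcripts of DAD1, a subunit of the oligosaccharyltransferase, SELENOM, a selenoprotein, and PPDPF were also lower, with log2 differences of -4.40 (SE 0.40), -4.35 (SE 0.61) and -4.29 (SE 0.67). Of the 12 highest and 12 lowest genes, RPL35 alone did not pass with the length trend removed (-1.08, adjusted p 0.0544 by limma).

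G3BP1 lies at chromosome 5, 151771045 to 151812785 on the plus strand of GRCh38. It stood at 227 CPM in FA anti-G3BP1, 233 in FA IgG, 851 in DSP anti-G3BP1 and 947 in DSP IgG, and rose 3.89-fold in DSP (log2 difference 1.96, SE 0.33, adjusted p 0.00413 by limma). Its level did not pass between the antibodies (-0.09, SE 0.33, adjusted p 0.994). The transcript G3BP1-201, of 2803 bases, carried most of its reads, at 172 and 191 CPM in FA and 638 and 740 CPM in DSP. G3BP1-202, of 10240 bases, stood at 52.5 and 41.6 CPM in FA and at 211 and 195 CPM in DSP. The paralog G3BP2 did not pass between the fixations (1.19, SE 0.47, adjusted p 0.0864).

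Long transcripts made up more of the DSP libraries. Transcripts of under 1 kb held 4.37% and 5.77% of matched reads in FA anti-G3BP1 and FA IgG, and 1.64% and 1.47% in DSP anti-G3BP1 and DSP IgG. Transcripts of 4 kb and over held 29.8% in each FA library and 38.2% and 35.1% in the DSP libraries. The genes with a main transcript of under 1 kb, such as RPL35, DAD1 and SELENOM, had a median log2 difference of -2.43 between the IgG libraries and of -2.38 between the anti-G3BP1 libraries. Genes of 2 to 4 kb, such as G3BP1 and HSPD1, had medians of 0.22 and 0.29. Of the called genes, 9 of under 1 kb were higher and 319 lower, and 549 of 4 kb and over were higher and 187 lower. A similar difference lay inside a single FA library, where the 2 recovered tables of FA IgG held 2.75% and 8.78% of reads in transcripts of under 1 kb. Those 2 tables differed at least 2-fold in 3125 genes, and the 2 tables of FA anti-G3BP1 in 1198.

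**Figure D3:**
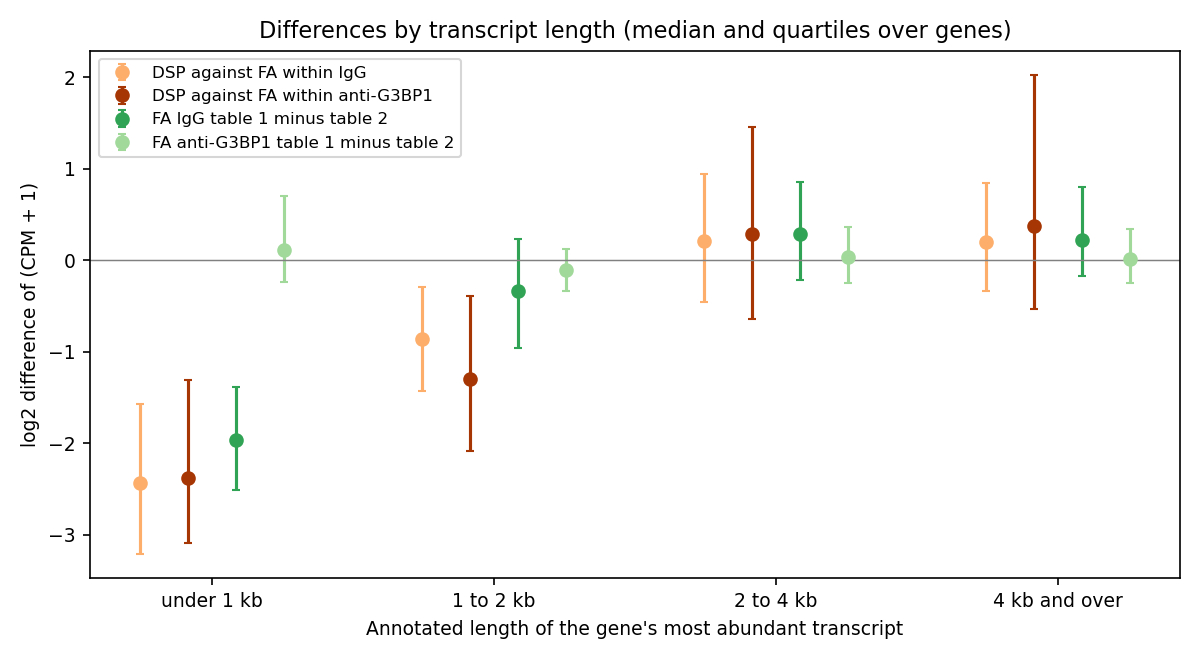
Points are median log2 differences of (CPM + 1) over genes by the annotated length of the gene's most abundant transcript, and bars span the quartiles. The differences DSP minus FA lie at -2.43 and -2.38 under 1 kb, the difference between the recovered tables of FA IgG lies at -1.96, and that of FA anti-G3BP1 at 0.11.

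Within single antibodies the same comparison rests on 1 library each and has no replicate check. HSPA5, ALDOA and RPL35 differed in the same direction in both pairs, with DSP minus FA log2 differences of 2.78, -2.46 and -5.09 in IgG and 2.54, -3.04 and -3.49 in anti-G3BP1. For several genes the anti-G3BP1 pair, with the library counted in fractions, gave most of the difference. In IgG alone ASPM stood at 1.38, TFRC at 3.80, IGF2R at 3.40, SYNCRIP at 2.05, CEBPG at 2.17, EBP at -1.75, RACK1 at -1.51, JUND at -2.28, APOBEC3C at -0.94, UCHL1 at -0.83 and ZNF703 at -2.35, each over 1.5 times less in fold than with both pairs. The same held for GABPB1-AS1, at -1.03 in IgG. Between DSP IgG and FA IgG, 3810 genes were at least 2-fold apart, 1799 higher and 2011 lower in DSP. Between DSP anti-G3BP1 and FA anti-G3BP1, 5778 were, 2944 higher and 2834 lower, or 4552 and 1297 on the deposited scale. Among the genes with 1 listed transcript the counts were 261 (58 higher and 203 lower) and 417 (73 and 344). For the edgeR fits that follow, DSP IgG holds 1 table and the spread comes only from the tables inside the FA files. Their p-values therefore measure no spread between samples. With edgeR on the 5 recovered tables of whole reads, 0 genes passed between DSP IgG and FA IgG (1863 at an unadjusted p under 0.05), 2015 passed when the first FA IgG table was left out, and 0 when the second was (2277 at an unadjusted p under 0.05).

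H2AZ2 as a gene did not pass between the fixations (log2 difference 0.50, SE 0.35, adjusted p 0.305 by limma), while its transcripts did. H2AFV-201, a transcript of 3804 bases of this histone variant gene (chromosome 7, 44826791 to 44848077, minus strand, 5 exons), was listed at 0 in both FA libraries and at 105 and 150 CPM in DSP (log2 difference 6.98, SE 0.59, adjusted p 6.13e-06 by limma). HSP90B1-201, the 18-exon transcript of an endoplasmic reticulum HSP90, rose by 2.96 (SE 0.37, adjusted p 5.06e-05). H2AFV-202, of 752 bases, fell by 2.40 (SE 0.41, adjusted p 0.000573). Of 16411 transcripts tested with limma, 3970 passed, 2031 higher and 1939 lower in DSP. On the deposited scale 2254 passed (1587 and 667), with edgeR 1349 (859 and 490), with a pseudocount of 5 2191, with the length trend removed 2635, and without limma's trend 0 (4087 at an unadjusted p under 0.05).

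Shares of transcripts within a gene differed between the fixations in 187 of 3844 genes, by at least 20 percentage points in the same direction under both antibodies. The share-weighted transcript length was over 100 bases longer in DSP IgG than FA IgG in 812 genes and shorter in 277. For the anti-G3BP1 libraries the counts were 795 and 721, and between the recovered tables of FA IgG 892 and 394. Shares were not corrected for length, so selection by length cannot be told apart from a change of isoforms. The H2AZ2 transcript H2AFV-201 went from 0% in both FA libraries, where 0 of 327 reads of the gene in FA anti-G3BP1 allow a Wilson upper limit of 1.16%, to 87.8% in DSP anti-G3BP1 and 86.1% in DSP IgG (82.7% to 88.9%). The transcript H2AFV-202, of 752 bases and with the same number of exons, went from 95.7% and 95.1% to 12.4% in DSP IgG. HSP90B1-201 went from 21.6% (18.9% to 24.5%) in FA anti-G3BP1 and 23.2% in FA IgG to 90.5% and 81.0% (78.9% to 83.0%) in DSP. The shorter HSP90B1-211, of 1127 bases and 8 exons, held 77.7% and 76.1% in FA.

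C5orf24-204, of 2923 bases, went from 0% in both FA libraries to 60.7% and 77.2%. The longer C5orf24-202, of 5065 bases, went from 100% in both FA libraries to 39.3% and 22.8%. In this gene the share therefore moved to the shorter transcript in DSP. The 43-exon transcript NUP205-201, which encodes a scaffold nucleoporin, went from 30.7% and 33.1% to 90.7% and 85.0% (80.0% to 88.9%). TBC1D31-201, with 22 exons, went from 25.6% and 10.3% to 66.0% and 66.7%. In ICE2, part of the little elongation complex, ICE2-202 went from 71.7% and 85.7% to 9.46% and 27.7%. In EPS15, an endocytic adaptor, EPS15-201 went from 72.1% and 53.4% to 0% in both DSP libraries, but between the 2 tables of FA IgG it stood at 0% and 84.4%. Between DSP IgG and FA IgG alone, 329 genes had such a difference, and between the 2 tables of FA IgG 593 did. The count was 67 at 30 percentage points and 78 in genes of at least 50 CPM.

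**Figure D4:**
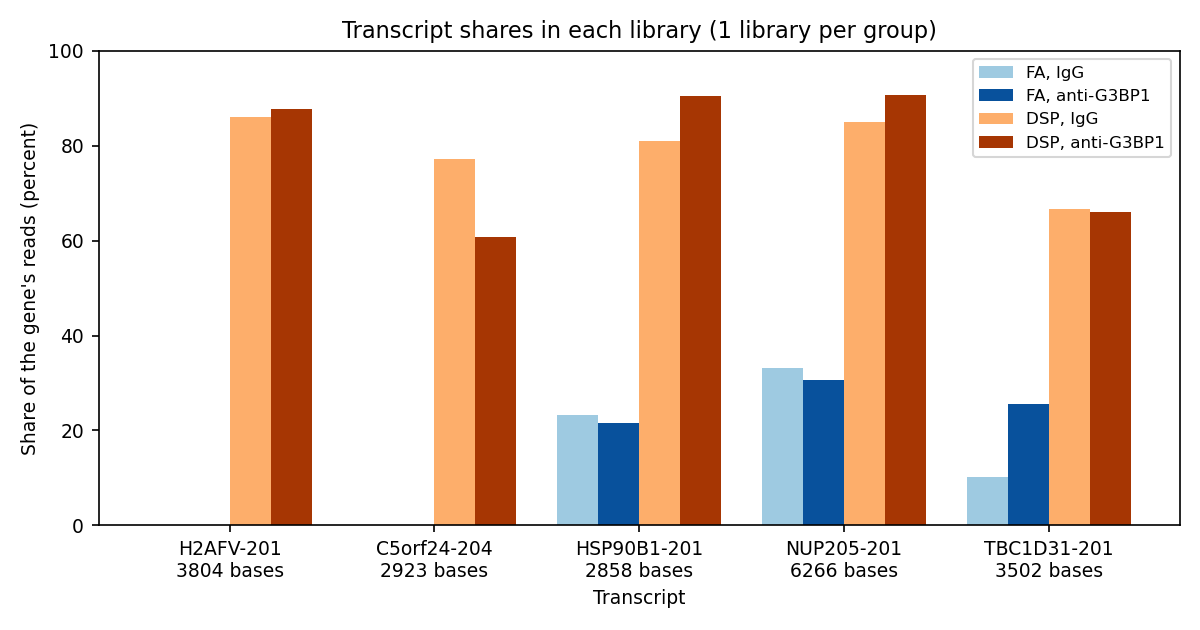
Bars give the share of a gene's reads (percent, axis from 0) held by the named transcript in each of the 4 libraries. H2AFV-201 and C5orf24-204 are at 0 in both FA libraries and at 60.7% or more in both DSP libraries.

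Anti-G3BP1 and IgG libraries were compared to see whether the antibody changed transcript abundance. No gene passed over both fixations. TMEM178B, a membrane protein gene at chromosome 7, 141074232 to 141480380, was listed at 0 in both anti-G3BP1 libraries and at 62.5 and 102 CPM in the IgG libraries (log2 difference -6.33, SE 0.74, adjusted p 0.066 by limma). In FA IgG its reads lay in 1 of the 2 recovered tables, 274 against 0. CLOCK, a circadian transcription factor, had a log2 difference of 4.49 (SE 0.73, adjusted p 0.381), SSH1, a cofilin phosphatase, 4.72 (SE 0.86, adjusted p 0.701) and GLB1L3 -3.51 (SE 0.55, adjusted p 0.381). Their reads also lay in single tables, 92 and 1 for CLOCK and 107 and 2 for SSH1 in FA anti-G3BP1, and 217 and 2 for GLB1L3 in FA IgG. Other genes were present in both tables of an FA library, ZC3H12B with 42 and 30 reads in FA anti-G3BP1 against 3 and 3 in FA IgG, and MTSS2 with 0 and 0 against 57 and 75, PTPRJ with 5 and 4 against 55 and 90, and PRTG with 0 and 0 against 246 and 149. ZBED10P, FSIP2, SP1, NBPF19, C1orf112 and ZC3H12B were the other genes of the 8 highest, and MTSS2, PRTG, VASH1, PTPRJ, ZNF282 and SMCR8 of the 8 lowest, with none passing.

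Of 10185 genes limma called 0 between the antibodies, with 428 at an unadjusted p under 0.05. edgeR called 0 (364 unadjusted) and DESeq2 12 (353 unadjusted). On the deposited scale limma also called 0 (140 unadjusted), with the median gene shifted by 0.34. limma called 163 genes without a filter, 62 at a mean of at least 20 CPM and 118 with the length trend removed. In the lists, 0 genes passed between the antibodies, over all genes or adjusted over the list alone. Ribosomal protein genes had a median of -0.47, those of oxidative phosphorylation -0.49, very long mRNAs 0.49 and stress granule proteins -0.03. The median of very long mRNAs was -0.03 within FA and 0.85 within DSP.

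Within FA, LRATD2 and NOTCH2, a Notch receptor, were listed at 0 in FA IgG and at 367 and 261 CPM in FA anti-G3BP1. PCDH9, a protocadherin, stood at 2.47 CPM in FA IgG and 319 CPM in FA anti-G3BP1. Both recovered tables held these differences, with 653 and 605 reads for LRATD2, 434 and 461 for NOTCH2 and 580 and 514 for PCDH9 in FA anti-G3BP1 against 0 and 0, 0 and 0, and 8 and 2 in FA IgG. These 3 genes stood at 191 CPM or more in both DSP libraries. PRTG, listed at 0 in FA anti-G3BP1, was at 104 CPM in FA IgG. In all, 804 of 10185 genes were at least 2-fold apart within FA, 389 higher and 415 lower with anti-G3BP1. Within DSP, MIR17HG, the host of a microRNA cluster, was listed at 0 in DSP IgG and at 225 CPM in DSP anti-G3BP1, and HS3ST3B1, a heparan sulfate enzyme, at 92.1 CPM and 0. Within DSP 2600 genes were at least 2-fold apart, 1905 higher and 695 lower with anti-G3BP1, or 3611 and 64 on the deposited scale. Among the genes with 1 listed transcript the direction turned, with 58 higher and 116 lower. These pairs have no replicate check, and DSP anti-G3BP1 was counted in fractions of reads. edgeR on the recovered tables called 0 genes between FA anti-G3BP1 and FA IgG (119 at an unadjusted p under 0.05), and 3, all higher, with the length trend removed. At a mean of at least 20 CPM the counts were 286 and 1510.

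Between the antibodies 3 of 16411 transcripts passed limma, all lower with anti-G3BP1 and named here after their values were seen. TMEM178B-202 had a log2 difference of -6.33 (SE 0.70, adjusted p 0.000966), NR2F2-202, from the gene of the nuclear receptor COUP-TFII, -6.00 (SE 0.77, adjusted p 0.00445) and GLB1L3-201 -5.75 (SE 0.84, adjusted p 0.0155). Each was listed at 0 in both anti-G3BP1 libraries. In FA IgG each rested on 1 of the 2 recovered tables, with 274 and 0 reads for TMEM178B and 217 and 2 for GLB1L3. NR2F2-202 held 72.8% of its gene in 1 of these tables and 0% in the other. With pseudocounts of 0.1 and 5 limma called 0 transcripts. edgeR called 0 transcripts (1123 at an unadjusted p under 0.05), DESeq2 165 and limma with TMM factors 169 (124 higher and 45 lower).

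Shares of transcripts differed between the antibodies in 13 of 3844 genes under both fixations. NR2F2-202 held 51.9% in FA IgG and 68.4% in DSP IgG (63.0% to 73.3%) and 0% in both anti-G3BP1 libraries, but within FA IgG it held 72.8% of 1 recovered table and 0% of the other. LYST-201, from a lysosomal trafficking gene, held every read with anti-G3BP1 under both fixations and 54.6% and 55.1% with IgG, but within FA IgG 43.3% of the first table and 94.4% of the second. SMAD2-201, from a TGF-beta signal transducer, held 49.1% and 25.8% with anti-G3BP1 and 78.6% and 56.8% with IgG, and SPART-203 held 38.2% and 58.0% against 73.6% and 81.9%. In the 2 tables of FA anti-G3BP1, SMAD2-201 held 0% and 61.8% and SPART-203 held 70.4% and 27.5%. In genes of at least 50 CPM the count was 0, and at 10 percentage points it was 138.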

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

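The rule behind this part takes genes at least 2-fold apart in opposite directions under the 2 fixations. It was applied after the data were seen, and no tests were made for it. Only the 3 highest and 3 lowest genes between the antibodies within each fixation were searched. How many of all tested genes meet the rule was not counted. ZNF704, a zinc finger gene, had a log2 difference between anti-G3BP1 and IgG of -6.45 within FA and of 6.72 within DSP. It was listed at 0 in FA anti-G3BP1 and in DSP IgG, and at 86.6 CPM in FA IgG and 104 CPM in DSP anti-G3BP1. NCR3LG1, a ligand of the natural killer cell receptor NKp30, had differences of 6.13 within FA and -6.63 within DSP. It was listed at 0 in FA IgG and in DSP anti-G3BP1, and at 69.3 CPM in FA anti-G3BP1 and 97.9 CPM in DSP IgG. Both genes were first picked for size, ZNF704 among the 3 lowest within FA and NCR3LG1 among the 3 lowest within DSP. Of the genes so picked, they were the ones whose sign turned at this size between the fixations. The difference between the fixations was not tested. In the library where each gene was present within FA, its reads lay almost entirely in 1 of the 2 recovered tables, 380 and 0 for ZNF704 in FA IgG and 1 and 235 for NCR3LG1 in FA anti-G3BP1. No biological explanation was tested.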

How the results depend on the processing

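The deposited scale was the main scale planned beforehand and became an alternative when the scale was changed. The length trend, the single-transcript genes, the libraries left out, at least 1 CPM in every library and the alternative share thresholds were chosen only after the files were read. So were edgeR and DESeq2 as run here, since the condition set for them was not met. No block for replicates could be fitted because each group had 1 library. The antibody term compares the fixations within each antibody, and the fixation term alone gave 2559 genes.

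Scale. With unassigned reads in the total, as planned beforehand, limma called 0 genes between the fixations (3190 at an unadjusted p under 0.05) against 2751. The low unassigned share shifts DSP anti-G3BP1 alone and enters the residual by construction. HSPA5, RPL35, G3BP1 and every other named gene lost its call. Transcripts went to 2254 from 3970, antibody transcripts to 0 (530 unadjusted) from 3, and the median of immediate early genes to 0.13 from -0.37. TMM factors gave 169 antibody transcripts. The cause was not tested for TMM.

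Length. With each library's length trend removed, 2635 transcripts were called between the fixations, and 118 genes and 154 transcripts between the antibodies. The median of snoRNA host genes turned to 0.76 from -1.42, and SNHG29 to 0.69 (adjusted p 0.228 by limma) from -2.12, since removing the trend raises short transcripts.

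Low values. limma called 163 antibody genes and 179 antibody transcripts without a filter, 62 and 43 at 20 CPM, and 3 and 0 (553 unadjusted) with at least 1 CPM in every library. Among the latter genes the median of glycolysis was -0.10 against 0.15, because HK2 and other genes under 1 CPM drop out. Pseudocounts of 0.1 and 5 left 0 antibody transcripts (797 and 413 unadjusted), and 5 left 2191 between the fixations. Genes 2-fold apart between the antibodies within FA numbered 337 at a pseudocount of 5, 1701 without a filter and 286 at 20 CPM, against 804. At 20 CPM, 1510 of 2600 were left within DSP and 2447 of 3810 between the IgG libraries.

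Genes with 1 listed transcript. Of 772 such genes, 178 were called between the fixations and 15 between the antibodies, and 70, 174, 261 and 417 were 2-fold apart within FA, DSP, IgG and anti-G3BP1. The set is smaller by construction, and a cause beyond that was not tested. The most abundant transcript alone gave 8 antibody genes.

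Tool. limma without its trend called 901 genes and 0 transcripts (4087 unadjusted) between the fixations and 0 antibody transcripts (292 unadjusted). edgeR called 1349 transcripts between the fixations and 0 between the antibodies (1123 unadjusted). DESeq2 called 12 antibody genes and 165 antibody transcripts. The cause was not tested.

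Shares. Between the fixations 78 genes differed at 50 CPM, 312 at 10 CPM, 544 at 10 percentage points and 67 at 30, against 187. Between the antibodies 0, 34, 138 and 2 did, against 13.

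Libraries left out. The fits had 1 term, since 2 terms leave 3 libraries no residual, and the lone library of a group was assumed to vary like the others. Against 2559 with 1 term on all libraries, fixation genes ranged from 487 without FA IgG, through 778 without FA anti-G3BP1, to 5293 without DSP IgG. Antibody genes were 0 each time (13 to 713 unadjusted).

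Of the checks of list medians, each a list under a setting, 142 stayed, 39 moved and 3 turned. A turn was counted only where both values exceeded the gap between the antibody arms. Some medians counted as stayed or moved therefore changed sign. Endoplasmic reticulum chaperones, for example, went from -0.10 to 0.08 between the IgG libraries (stayed) and to 0.40 on the deposited scale (moved). Of the checks on named genes between the fixations, 621 were the same, 35 weaker, 10 stronger and 1 turned. With edgeR the calls of ZNF703, GABPB1-AS1, OIP5-AS1, HSPB1, IER2, IFIT5, TNFRSF10B, APOBEC3C, UCHL1, FBLN1 and KRT18 were lost, with a pseudocount of 5 those of IER2, IFIT5 and FBLN1, with TMM that of FBLN1, and on the most abundant transcript those of FMR1, IGF2R and VPS13D. For named genes between the antibodies 114 were the same and 20 stronger. For genes of single pairs 38 stayed and 22 moved.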

Other observations

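The families in the first 2 paragraphs and most tests below were chosen only after the results were seen, and the exceptions, set before, were the comparison of genes with several and single transcripts, the antibody effect shared by both fixations and the lengths of genes listed at 0. Aminoacyl-tRNA synthetases, which charge tRNAs, had a median log2 difference of 0.92 between DSP and FA, with 8 of 18 higher and 0 lower. IARS1 rose by 3.93 (SE 0.56) and LARS1 by 2.75 (SE 0.50), and TARS1 rose too. Nucleoporins had a median of 0.59, with 6 of 20 higher and 0 lower, among them NUP153 (3.77, SE 0.74), NUP107 and NUP93. Kinesins had a median of 0.84, with 8 of 24 higher and 2 lower, and KIF14, KIF15 and KIF2C rose by 3.62, 2.42 and 2.34. With the length trend removed, 3 nucleoporins and 4 kinesins were lower, 6 and 8 were higher, and the median of kinesins was 0.41. Between the IgG libraries alone IARS1 stood at 2.58, NUP153 at 1.99 and KIF14 at 2.53. Among genes with a ZNF symbol, taken as C2H2 zinc finger genes, the median was 0.92. Of these 282, 44 rose and 10 fell, against 1314 and 1437 of 10185 over all genes. Random lists matched on length and expression had medians of 0.22 for the synthetases and 0.12 for the nucleoporins. Those for the kinesins and the zinc finger genes were 0.37 and 0.40.

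Sm and LSm genes, which encode the ring proteins of spliceosomal RNPs, had a median of -2.41, with 12 of 19 lower and 0 higher. SNRPD2 (-3.97, SE 0.45), LSM7 (-3.19), LSM3 (-3.15) and LSM2 (-2.88) were the lowest. Proteasome genes had a median of -1.36 and went both ways by subunit, with 18 of 32 lower and 3 higher. PSMB3 (-3.58, SE 0.40) and PSMB6 (-3.34), of the catalytic core, were lower, and PSMD1 (3.09, SE 0.76, and 2.14 between the IgG libraries), a large subunit of the regulatory particle, was higher. Genes of the chaperonin CCT had a median of 0.38, and CCT8 alone rose (1.08, SE 0.34). Solute carriers were split, with 14 of 152 higher and 16 lower. With the length trend removed the medians of Sm and LSm genes and of proteasome genes were -0.68 and -0.41, and on the deposited scale none of these genes passed. The trend-removed calls were 6 lower and 1 higher for Sm and LSm genes and 8 lower and 2 higher for proteasome genes. Random lists matched on length and expression had medians of -1.07 and -0.80.

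The fall of RPL35, NDUFA13 and SNRPD2 and the rise of long transcripts between FA and DSP may come in part from selection by length during extraction or library making. The difference between DSP IgG and FA anti-G3BP1 correlated with that between the 2 tables inside FA IgG across genes (Pearson r 0.412, genes not being independent replicates). The correlation holds no length term, so it cannot single out length among other differences common to both comparisons. Against length as the whole explanation, 59.9% of the called genes, 1648 of 2751, passed with the same sign once each library's length trend was removed. Fractional counting in DSP anti-G3BP1 as the whole explanation is argued against by the difference between the IgG libraries, both of whole reads, which correlated with that between the anti-G3BP1 libraries across all 10185 genes (Pearson r 0.669), with no library in common. Spread between tables stays open for the IgG pair, since 3125 genes were 2-fold apart inside FA IgG against 3810 between the IgG libraries, whereas inside FA anti-G3BP1 1198 were, against 5778 between the anti-G3BP1 libraries, and no such spread is known for DSP.

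Within DSP, 2600 genes were 2-fold apart between the antibodies, MIR17HG and HS3ST3B1 among them, against 804 within FA. The 2 counts are not alike, since each FA file is the mean of 2 tables and each DSP file holds 1. Single tables were 2-fold apart in 3125 genes inside FA IgG and in 1198 inside FA anti-G3BP1, so spread between tables stays open here too. An antibody effect shared by both fixations could have produced part of this, but the differences within FA and DSP did not go together across genes (Pearson r -0.0224, genes not being independent replicates). Fractional counting of reads between transcripts is a candidate explanation that cannot be told apart from an effect of the sample. In DSP 29.6% of genes with several transcripts and 22.5% of matched genes with 1 were 2-fold apart, a ratio of 1.31, and in FA the shares were 10.6% and 9.07%. That ratio takes no account of direction, which differed. Within DSP, 58 genes with 1 listed transcript were higher with anti-G3BP1 and 116 lower, against 1905 and 695 over all genes, without matching on expression. The design holds no replicate of DSP anti-G3BP1, and no biological explanation was tested.

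In 1 of the 2 tables of FA IgG, 51 of 4818 genes that had at least 20 CPM in every other table were listed at 0, among them ETNK1, an ethanolamine kinase, DYRK2, a kinase, AP1G1, a clathrin adaptor, and MED1, a Mediator subunit. The other tables had 8, 4, 6, 2 and 1 such genes. Against too few reads, the table closest in depth, with 1711036 assigned reads against 1553350, had 8 of 4594 genes at 0 under the same filter, a share 6.08 times smaller. A loss that depends on length may contribute, as their main transcripts had a median of 5909 bases against 3076 in the other genes, a ratio of 1.92. What else separates the 2 tables stays open, and no biological explanation was tested.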
